A study of Mus musculus with 7 samples.

How the data were processed

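Transcripts of mouse spleen cells were measured on 7 Affymetrix oligonucleotide arrays, with 10 µg of RNA labelled per array. The deposited values are MAS5 signal intensity per probe set on a linear scale, per the submitters' processing notes; the notes give no MAS5 version. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The 2% trimmed means of the 7 arrays lay between 500.18 and 500.19, a ratio of 1.00002 between the highest and the lowest, within the tolerance of 5% set for using the signals without further scaling. Array medians ran from 145.3 to 174.3. For arrays, the number of arrays limits the precision of each value.

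Of 22690 probe sets, 64 are manufacturer controls and 22626 remained. Exactly 1 gene symbol was assigned to 20380 probe sets, several symbols to 691 and none to 1555. Gene IDs of 20364 probe sets matched the reference annotation of mouse genes and no symbol needed an update. The probe sets with 1 symbol cover 12394 genes. Signals were analysed as log2(signal + 50), so fold changes of genes with low signal are understated. A probe set was tested when the mean of at least 1 group reached the 40th percentile of all signals, which left 15494 probe sets and 9017 genes with a single symbol. Probe sets with several symbols or none were tested but not named. Certain items are not reported here.

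The groups were syngeneic (1 array), allogeneic with isotype antibody (2), allogeneic with anti-ICOSL antibody from day 0 (2) and allogeneic with anti-ICOSL antibody from day 3 (2). The 4 comparisons came from 1 fit over all 7 arrays: isotype against syngeneic, day 0 against isotype, day 3 against isotype, and day 0 against day 3. The fit used limma 3.58.1 in R 4.3.3, with 3 residual degrees of freedom and a prior of 3.38 degrees of freedom. The lone syngeneic array was assumed to vary like the arrays of the other groups. P-values were two-sided and adjusted by Benjamini and Hochberg over the tested probe sets of a comparison, with a threshold of 0.05. Errors of log2 changes are standard errors (SE) of the fit. Means of signals carry the standard deviation (SD) of n = 2 arrays, and the syngeneic value is a single array without SD.

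Fixed gene lists (24, with 490 members, of which 416 had a probe set) cover costimulation, T cell markers, cytotoxic effectors, helper T cell cytokines and regulators, regulatory T cells, interferon gamma response, type I interferon response, proliferation, B cell markers, plasma cells, macrophages and monocytes, neutrophils and granules, dendritic cells, natural killer cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, stroma and endothelium, homing and chemokine receptors, p53 response, glycolysis, MHC class I and antigen processing, MHC class II, and the strain haplotype that separates C3H from B6. Each list was tested with camera, which compares its members with all other tested genes, at a preset correlation of 0.01, with 1 probe set per gene (that with the highest mean) and at least 5 tested members. Camera was also run with the correlation estimated from the data, and fry was run beside it. P-values of lists were adjusted over the 24 lists of a comparison. Counts of members that passed are given over all tested probe sets and adjusted over the list alone.

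Genes were named by a rule with 1 probe set per gene: the 10 largest rises and the 10 largest falls that passed the test with arrays of the groups not overlapping, or the 5 largest in each direction where fewer passed; up to 4 members of each list with the largest absolute change; and always Icos, Icosl, Ifng, Gzmb, Prf1, Foxp3, Il10, Il4, Cd4 and Cd8a. Some further list members, such as those behind a small count or past the threshold only adjusted over the list alone, are also named and were chosen after their values were seen: Ccl5, Cd86, Psmb9, Ccr2, Tnfrsf4, Prdm1, Ccr7, Klra7, C1qa, Ncr1, Gata1, Epor, Klf1, Ermap, Lyz2, H2-D1, Bcl6, Cxcr5, Izumo1r, Pf4, Cxcl13, Il21 and Pdcd1 in the comparisons where the rule does not name them. The groups, comparisons, lists, naming rule and alternative settings were fixed before the data were examined. The alternative settings were pseudocounts of 16 and 100, a filter at the 60th percentile or none, quantile normalization, median centring, the replicate number as a block, a fit to the compared groups alone, limma with trend and robust options, and leaving out each array. Both comparisons of an anti-ICOSL group with isotype use the same isotype arrays, so their overlap was set against 100 simulations with shared controls and no effect. Shifts of genes that differed between isotype and syngeneic arrays were measured by choosing genes at a change of 4-fold on 1 isotype array and measuring them against the other, with 10000 random lists as background.

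The procedure was tested on simulated data with 200 changed probe sets per draw. Noise was normal, with spreads taken from the fit after limma had drawn those of single probe sets toward a common value. Simulated spreads therefore differed less between probe sets than the fitted ones, and recovery in the data may be lower. With a change of 4-fold, 85.8% were recovered for isotype against syngeneic, 93.4% for day 0 against isotype, 90% for day 3 against isotype and 91.8% for day 0 against day 3. With a change of 2-fold, the shares were 6.8%, 27.4%, 30.2% and 25.8%. False calls per draw numbered 8.8, 9.4, 10 and 11.2 in the same order. In each of the 4 comparisons these are a larger share of the calls than the threshold of 0.05 allows for. Groups hold fewer than 3 arrays, so no count of other splits was made and no search for single aberrant arrays within a group was run.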

Results

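Acute graft-versus-host disease arises when donor T cells attack the recipient after an allogeneic transplant. ICOS is a costimulatory receptor of activated T cells, and its ligand ICOSL is carried by B cells, macrophages and other antigen-presenting cells. Female C57BL/6 (B6) mice aged 9 to 12 weeks received 10.0 Gy of irradiation and, 4 to 6 h later, splenocytes from C3H donors, which differ in their MHC (allogeneic), or from B6 donors (syngeneic). Allogeneic recipients were given a control antibody of the same isotype or an antibody against ICOSL (500 µg at first, then 200 µg every other day) that started on day 0 or on day 3. Controls received the same doses, but the day on which the isotype antibody started is not stated. Differences from isotype may therefore also hold a difference in the timing of injections. Spleens were taken on day 4 and transcript levels were measured on 7 arrays: 1 syngeneic, 2 isotype, 2 anti-ICOSL day 0 and 2 anti-ICOSL day 3. RNA of allogeneic mice was combined before it was put on the 2 arrays of a group, so every p-value measures the spread between arrays only, which may be technical. Donor strain and the allogeneic response cannot be separated in the comparison with the syngeneic array.

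Array medians lay between 145.3 and 174.3 signal units after scaling to trimmed means of 500.18 to 500.19. Of 15494 tested probe sets, 661 differed at least 2-fold between the isotype arrays, 492 between the day 0 arrays and 479 between the day 3 arrays. The ratio of the 3' to the 5' control probe set of Gapdh, a sign of RNA quality, was 0.957 on the syngeneic array, 0.784 and 0.767 on the isotype arrays, 0.794 and 0.821 on the day 0 arrays, and 0.838 and 0.865 on the day 3 arrays. The same ratio for Actb was 0.967 to 1.028 on the 7 arrays.

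The comparison of isotype with syngeneic arrays asks how the spleen of an allogeneic recipient differs from that of a syngeneic one on day 4. As lists, costimulation, cytotoxic effector and proliferation genes were higher, and macrophage, neutrophil and erythroid genes were lower, with 8 of 21, 9 of 21 and 5 of 31 members that rose and 22 of 24, 10 of 16 and 7 of 16 that fell. Camera called 13 of 24 lists at its preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.0540). The second run rests on few degrees of freedom, so the lost calls do not show that correlated members made them. Estimates fell below the preset 0.01 for lists such as glycolysis (−0.055), B cell markers (−0.061), neutrophil genes (−0.031) and costimulation (−0.030). For these lists the values argue against correlation as the reason for the lost call. Other lists, such as macrophage (0.054) and MHC class II genes (0.215), had higher estimates, and for them this stays open. Gzmb, a protease that killer lymphocytes release into target cells, rose 8.94-fold from 3059 to 27852 ± 3211 (SD, n = 2), and Ifng, the cytokine interferon gamma, rose 13.6-fold from 132 to 2435 ± 244. Icos, the receptor under study, rose 8.03-fold from 480 to 4213 ± 240. Slc40a1, the iron exporter of macrophages that break down red cells, fell from 10891 to 826 ± 71. Limma called 1028 probe sets, which cover 783 genes, 387 of them higher and 641 lower in isotype. At least 2-fold apart with arrays not overlapping were 1707 probe sets, 583 higher and 1124 lower (1704 to 2349 with 1 array left out). Arrays of the groups did not overlap for 76.8% of tested probe sets, where chance gives 66.7%.

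With 1 probe set per gene, the largest rise was that of Gbp2b, a guanylate-binding protein induced by interferon (log2 change 4.53 ± 0.20 SE, adjusted p = 0.00134; 2611 ± 2 against 65). Gzmk, a granzyme, came next (4.34 ± 0.20, adjusted p = 0.00134). It was followed by Zbtb32, a transcriptional repressor of lymphocytes (4.07 ± 0.26, adjusted p = 0.00205), and Ifi202b, an interferon-inducible DNA-binding protein whose level also differs between mouse strains (4.04 ± 0.20; 1500 ± 37 against 44). Ccnb1ip1 (3.80), Ifng (3.77), Emp1 (3.59), Pdcd1 (3.39), Il2ra (3.25) and Havcr2 (3.21) complete the 10 largest named rises. Pdcd1 is the inhibitory receptor PD-1 and Il2ra is the alpha chain of the interleukin 2 receptor. Among the 10 largest named falls, Igha, the constant region of IgA heavy chains, stood at 2117 ± 465 against 46620 (−4.45 ± 0.25, adjusted p = 0.00134). C1qtnf12 (−4.25), Pla2g7 (−4.25), Apoe (−3.91), Rpgrip1 (−3.84), Slc40a1 (−3.65), Sash1 (−3.55), Vcam1 (−3.53), Chil3 (−3.52) and Hebp1 (−3.46) followed. Of these 20 genes, 17 passed under every alternative setting. The call of Pdcd1 ended without isotype array 2 (adjusted p = 0.0518), that of Sash1 under 6 settings that include each isotype array left out (highest adjusted p = 0.0913), and that of Hebp1 under 4 (highest adjusted p = 0.0665).

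Costimulation genes were higher as a list (16 of 21 members higher, mean log2 change 1.14, camera adjusted p = 1.3e-06; adjusted p = 0.0540 with an estimated correlation). Of its members 8 rose and 1 fell over all probe sets, against 12 and 1 adjusted over the list alone. Ctla4, an inhibitory receptor that competes with CD28, rose from 193 to 1664 ± 305, and Havcr2 (TIM-3), another inhibitory receptor, rose from 57 to 939 ± 58. Cd86, a ligand of CD28 on antigen-presenting cells, fell (−1.70, adjusted p = 0.0274; up to 0.0773 without isotype array 2 or either day 0 array). The cytotoxic effector list was higher as well (14 of 21 members higher, mean 0.69, adjusted p = 0.00306; adjusted p = 0.0919 with an estimated correlation), with 9 members that rose and 1 that fell, or 11 and 4 adjusted over the list alone. Prf1, which encodes the pore-forming protein perforin, rose from 618 to 3033 ± 79, Serpinb9, an inhibitor of granzyme B, rose from 748 to 3842 ± 178. The chemokine Ccl5 fell (−1.75, adjusted p = 0.00723). Helper T cell cytokines and regulators were higher (15 of 18 members, mean 0.97, adjusted p = 6.5e-05; adjusted p = 0.0919 with an estimated correlation), with 6 that rose and 1 that fell, or 8 and 1 adjusted over the list alone. Il21, a cytokine that acts on B cells and killer T cells, rose from 4 to 420 ± 117. Il12rb2, the receptor chain for interleukin 12, rose from 108 to 479 ± 82. The member that fell was Il4 (29 ± 2 against 107, adjusted p = 0.0428), whose call ended under 12 of the 14 alternatives, among them each allogeneic array left out (up to adjusted p = 0.110).

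The T cell marker list was higher (12 of 17 members, mean 0.34, adjusted p = 0.0153; adjusted p = 0.327 with an estimated correlation), and its call ended without isotype array 1 (adjusted p = 0.154). Of its members 5 rose, against 8 that rose and 1 that fell adjusted over the list alone. Cd4, the coreceptor of helper T cells, rose from 815 to 2423 ± 16 (1.52 ± 0.20, adjusted p = 0.0118). The call of Thy1, another of the 5, ended without either isotype array and without either day 3 array. Cd8a was 3151 ± 1571 against 3272 (−0.15, adjusted p = 0.889). Interferon gamma response genes were higher (17 of 20 members, mean 0.48, adjusted p = 2.0e-04; adjusted p = 0.0783 with an estimated correlation), and 3 rose, or 7 adjusted over the list alone. Gbp2 (1.08), the immunoproteasome subunit Psmb9 (0.97) and the feedback inhibitor Socs1 (1.01) were those 3, and each of these calls ended with any 1 allogeneic array left out (up to adjusted p = 0.0803, 0.0979 and 0.134). All 31 proliferation genes were higher (mean 0.73, adjusted p = 3.5e-11; adjusted p = 0.0540 with an estimated correlation), with 5 that rose, or 20 adjusted over the list alone. Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose from 3314 to 8029 ± 63, a call that ended without either isotype array (up to adjusted p = 0.0604). The calls of Plk1 and Aurkb, 2 more of these 5, ended without either isotype array as well. That of Plk1 also ended without either day 3 array, and that of Aurkb with any 1 allogeneic array left out. All 15 glycolysis genes were higher (mean 0.84, adjusted p = 8.8e-08; adjusted p = 0.0540 with an estimated correlation), with 8 that rose, or 9 adjusted over the list alone. Hif1a, a transcription factor that drives glycolytic genes, rose from 1753 to 5813 ± 66 (1.70 ± 0.20, adjusted p = 0.00723). The calls of Pfkp, Pkm and Hk2, 3 of these 8, ended without either isotype array, and that of Hk2 with any 1 allogeneic array left out.

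The macrophage and monocyte list had the lowest median of the 24 lists (23 of 24 members lower, median −2.49, adjusted p = 3.6e-24; adjusted p = 0.0540 with an estimated correlation), and 22 fell, or 23 adjusted over the list alone. Vcam1, an adhesion molecule of red pulp macrophages and stroma, fell from 8748 to 716 ± 61, Hmox1, which degrades haem, fell from 7111 to 628 ± 10. Spic, the transcription factor of red pulp macrophages, fell from 2262 to 172 ± 41. Ccr2, a receptor of inflammatory monocytes, had a log2 change of 0.41 (adjusted p = 0.261). Neutrophil and granule genes were lower in 16 of 16 members (median −1.67, adjusted p = 5.2e-11; adjusted p = 0.0540 with an estimated correlation), and 10 fell, or 14 adjusted over the list alone. S100a9, an abundant calcium-binding protein of neutrophils, fell from 9572 to 2072 ± 116, and Camp, an antimicrobial granule peptide, fell from 2678 to 433 ± 91. Erythroid genes were lower in 15 of 16 members (median −1.34, adjusted p = 1.2e-08; adjusted p = 0.0783 with an estimated correlation), and 7 fell, or 12 adjusted over the list alone. Klf1, the master regulator of red cell genes, fell from 3200 to 755 ± 62. The carbonic anhydrase Car2 fell from 13112 to 3411 ± 36, and the call of Tal1, another of the 7, ended without either isotype array (up to adjusted p = 0.0600). B cell markers were lower in 14 of 15 members (median −0.55, adjusted p = 0.00271; adjusted p = 0.0919 with an estimated correlation), and Fcer2a (CD23) and Spib fell, or 3 members adjusted over the list alone. Without isotype array 1 the call of Fcer2a ended (adjusted p = 0.0527), and that of Spib ended with any 1 allogeneic array left out (up to adjusted p = 0.119).

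Genes of MHC class II were lower in 9 of 9 members (median −0.82, adjusted p = 1.7e-05; adjusted p = 0.127 with an estimated correlation), and H2-Ab1, Ctss and H2-DMb2 fell, or 8 adjusted over the list alone. H2-Ab1 stood at 906 ± 254 against 4663, and the calls of Ctss and H2-DMb2 ended with any 1 allogeneic array left out (up to adjusted p = 0.0828 and 0.133). A further probe set of H2-Aa had a log2 change of −0.09 (adjusted p = 0.857), against −0.82 for the counted one. Further probe sets of H2-Ab1 were lower as well (−1.29 and −1.49). The list of genes that separate the C3H from the B6 haplotype was lower (5 of 6 members, mean −1.21, adjusted p = 0.00208; adjusted p = 0.0919 with an estimated correlation), with 1 that rose and 3 that fell, or 1 and 5 adjusted over the list alone. H2-Ea, which B6 mice do not express, was 272 ± 39 against 56 (1.60, adjusted p = 0.0202; up to adjusted p = 0.0701 without either isotype array). The probe sets of H2-D1 went opposite ways. The named one fell from 24785 to 4127 ± 187, and a further one, with the largest rise of any probe set (5.31, adjusted p = 9.4e-04), stood at 39 on the syngeneic array against 3460 and 3456 on the isotype arrays. Probe sets of H2-K1 ran from −3.70 (adjusted p = 0.00267) to 0.23 (adjusted p = 0.651). MHC class I and antigen processing genes differed in sign between median (0.11) and mean (−0.17) and did not pass (adjusted p = 0.985), with 2 that rose and 3 that fell, or 3 and 3 adjusted over the list alone.

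The other 10 lists did not pass for isotype against syngeneic. Camera gave adjusted p = 0.0919 for regulatory T cells (4 of 10 rose, 5 rose and 3 fell adjusted over the list alone), 0.0919 for mast cells with basophils and eosinophils, 0.186 for dendritic cells, 0.277 for the p53 response, 0.311 for homing and chemokine receptors, 0.531 for megakaryocytes and platelets, 0.610 for natural killer cells, 0.961 for stroma and endothelium (median 0.08, mean −0.02), 0.985 for plasma cells and 0.985 for the type I interferon response. Single members did. Il2ra and Tnfrsf4 (OX40) rose among regulatory T cell genes, and Prdm1, the regulator of plasma cell and effector T cell fate, rose from 268 to 799 ± 9. Ccr7, a homing receptor for lymph nodes, fell from 1425 to 345 ± 86, and the natural killer receptor Klra7 fell from 471 to 44 ± 10. Without isotype array 2 the calls of Tnfrsf4 (adjusted p = 0.0532) and Ccr7 (0.0797) ended, and without either isotype array that of Prdm1 (up to 0.0519). Foxp3 had a log2 change of 0.02 (adjusted p = 0.976), Icosl −0.33 (adjusted p = 0.461) and Il10 1.02 (adjusted p = 0.120). The 16 exocrine pancreas transcripts, a list made after the values were seen, were lower on the isotype arrays in 13 members (median −0.65), and the Gapdh ratio was lower as well. Fitted to the isotype and syngeneic arrays alone, 318 probe sets passed, and the calls of Cd4 (adjusted p = 0.0615), Hif1a (0.0501) and Il12rb2 (0.0569) ended. Further calls that this fit ended include those of Cd28, Tnfrsf4, Prdm1, Thy1, Gbp2, Socs1, Rrm2, Plk1, Aurkb, Pfkp, Pkm and Hk2. They also include those of Il4, Ctss, Spib, H2-DMb2, H2-Ea, Ccr7, Fcer2a and Hebp1. With 1 syngeneic array, the number called depended on single arrays. It was 490 without isotype array 1, 406 without isotype array 2 and 665 to 679 without any other allogeneic array. Centring each array on its median moved the median change of all probe sets from −0.01 to 0.11 and the share of called probe sets that were higher from 37.6% to 48.9%.

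**Figure D1:**
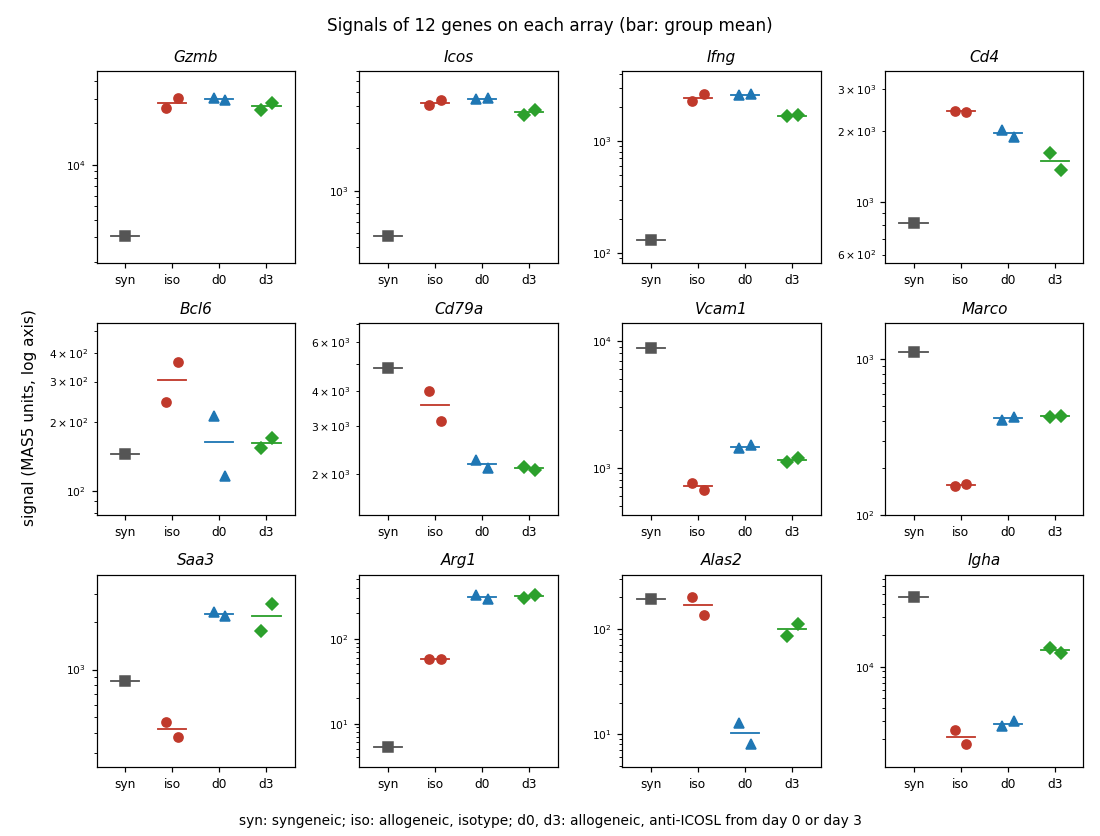
MAS5 signal of 12 genes on each of the 7 arrays by group, on a log axis, with 1 point per array and a bar at the group mean. Gzmb stands at 3059 on the syngeneic array and at 27852 as the isotype mean, and Igha at 2117 in isotype against 14454 in day 3.

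The comparison of day 0 with isotype arrays asks what blockade of ICOSL from the time of transplant changes in the allogeneic spleen. No single gene passed, while macrophage and monocyte markers were higher as a list and B cell markers were lower. Neither call held with an estimated correlation (adjusted p = 0.168 for each). The macrophage list was higher in 23 of 24 members (median log2 change 0.55, adjusted p = 8.7e-15). Marco, a scavenger receptor of marginal zone macrophages, was 417 ± 15 against 156 ± 2 (SD, n = 2), and Vcam1 was 1463 ± 58 against 716 ± 61, compared with 8748 on the syngeneic array. Icos was 4499 ± 28 against 4213 ± 240 and Gzmb was 29793 ± 806 against 27852 ± 3211. Limma called 0 of 15494 probe sets (smallest adjusted p = 0.0858), and 1125 had an unadjusted p under 0.05, where chance gives 775. At least 2-fold apart with arrays not overlapping were 204 probe sets, 122 higher and 82 lower. In the 100 simulations with no effect the mean count was 168. Arrays of the groups did not overlap for 35.6% of tested probe sets, where chance gives 33.3%. The count changed little without a day 3 array. It was larger without an array of either group compared, where that group holds 1 array. Called probe sets numbered 4 at a pseudocount of 100, 13 with the filter at the 60th percentile and 21 with trend and robust options.

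The 5 largest named increases, none of which passed, were those of Saa3, an acute-phase protein (2.28 ± 0.23, adjusted p = 0.117; 2235 ± 72 against 421 ± 65) and Syt8 (1.81, adjusted p = 0.591), then Arg1, the arginine-degrading enzyme of alternatively activated macrophages (1.75 ± 0.16, adjusted p = 0.0858; 313 ± 24 against 58 ± 1), Clec10a, a lectin of macrophages and dendritic cells (1.70, adjusted p = 0.0858) and Sema4f (1.55, adjusted p = 0.622). With the filter at the 60th percentile Saa3 (adjusted p = 0.0144), Arg1 (0.0103), Marco (0.0328) and Cpb1 (0.0144), which was lower, passed. The 5 largest decreases were those of Cpb1 (−1.98, adjusted p = 0.117), Cpa1 (−1.91, adjusted p = 0.221), Alas2, the first enzyme of haem synthesis in red cells (−1.84, adjusted p = 0.148; 10 ± 3 against 168 ± 47), Cela2a (−1.80, adjusted p = 0.192) and Lce1h (−1.65, adjusted p = 0.337). Cpb1, Cpa1 and Cela2a encode digestive enzymes of the exocrine pancreas. The median signal of the 16 exocrine pancreas transcripts was 419 on the syngeneic array, 227 and 233 on the isotype arrays, 117 and 130 on the day 0 arrays and 135 and 138 on the day 3 arrays. Both day 0 arrays also had a higher Gapdh ratio (0.794 and 0.821) than the isotype arrays (0.784 and 0.767).

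In the macrophage and monocyte list 0 members passed over all probe sets and 12 passed adjusted over the list alone, all higher, among them C1qa (0.88) of the complement system and the iron exporter Slc40a1 (0.89). B cell markers were lower in 13 of 15 members (median −0.44, adjusted p = 1.5e-05; adjusted p = 0.168 with an estimated correlation), with 0 that passed over all or adjusted over the list alone. Cd79a, a chain of the B cell receptor complex, was 2179 against 3569 (−0.69, adjusted p = 0.559) and Cd22, an inhibitory coreceptor, changed by −0.58 without passing. Type I interferon response genes were lower in 15 of 21 members (median −0.24, adjusted p = 0.00316; adjusted p = 0.263 with an estimated correlation), and Ifit1, an antiviral RNA-binding protein, passed adjusted over the list alone (840 ± 10 against 1478 ± 59). This list call ended without isotype array 1 (adjusted p = 0.0672). Erythroid genes were lower in 12 of 16 members (median −0.20, adjusted p = 0.00914; adjusted p = 0.468 with an estimated correlation), with Alas2 past the threshold adjusted over the list alone. The erythroid call ended without isotype array 1 (adjusted p = 0.0526) or day 0 array 2 (0.257). Neutrophil and granule genes were higher in 13 of 16 members (median 0.31, adjusted p = 0.0338; adjusted p = 0.378 with an estimated correlation), with 0 adjusted over the list alone. The neutrophil call ended without isotype array 1 (0.354), day 0 array 1 (0.331) or day 0 array 2 (0.0806).

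The other 19 lists did not pass for day 0 against isotype. The smallest adjusted p among them was 0.136, for natural killer cells. Cytotoxic effectors (0.961), costimulation (0.909), T cell markers (0.164), helper T cell cytokines and regulators (0.570), regulatory T cells (0.917), the interferon gamma response (0.961), proliferation (0.889) and MHC class II (0.384) lay further from the threshold. Adjusted over the list alone, Il4 passed among helper genes (98 ± 10 against 29 ± 2), as did Ncr1 among natural killer genes and H2-D1 in the strain haplotype list. The Il4 signal in isotype lay below the 25th percentiles of the isotype arrays (39.6 and 46.6). Of 7 other H2-D1 probe sets, 3 had the same sign. Median, mean and test differed in sign for the homing, interferon gamma response, mast cell, regulatory T cell and strain haplotype lists, whose medians lay between −0.02 and 0.02. The log2 changes of Ifng (0.09 ± 0.16), Prf1 (−0.07 ± 0.17), Cd4 (−0.30 ± 0.17), Cd8a (−0.08 ± 0.38), Foxp3 (−0.15 ± 0.19), Icosl (−0.03 ± 0.19) and Il10 (0.69) did not pass, with adjusted p of 0.932, 0.954, 0.778, 0.979, 0.910, 0.980 and 0.672.

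**Figure D2:**
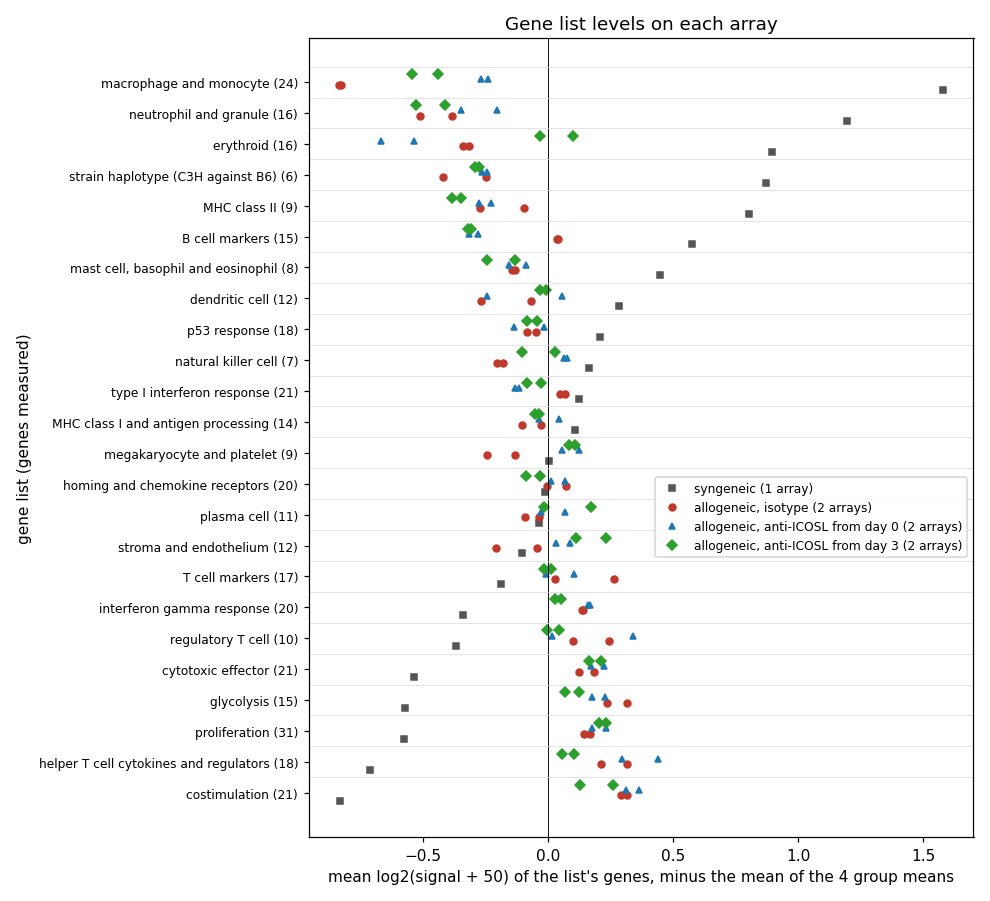
Mean log2 level of each gene list on each of the 7 arrays, relative to the mean of the 4 group means, by group, with 1 point per array. Macrophage and monocyte markers lie at 1.58 on the syngeneic array, −0.83 and −0.84 on the isotype arrays, −0.24 and −0.27 on the day 0 arrays and −0.44 and −0.54 on the day 3 arrays.

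The comparison of day 3 with isotype arrays asks what a later start of the antibody, the day before harvest, changes. Macrophage and monocyte markers and erythroid genes were higher as lists, and 6 lists were lower, among them B cell markers, T cell markers and MHC class II genes. None of these 8 calls held with an estimated correlation (adjusted p = 0.360 for each). Igha, the IgA heavy chain, was 14454 ± 1093 against 2117 ± 465 (SD, n = 2; 2.76 ± 0.20, adjusted p = 0.0959), with 2 further probe sets of the same sign, compared with 46620 on the syngeneic array. Marco was 431 ± 4 against 156 ± 2 and Cd79a was 2105 against 3569. Limma called 0 of 15494 probe sets (smallest adjusted p = 0.0959), and 1601 had an unadjusted p under 0.05, where chance gives 775. At least 2-fold apart with arrays not overlapping were 290 probe sets, 222 higher and 68 lower. The mean count in the 100 simulations with no effect was 170. Arrays of the groups did not overlap for 43.2% of tested probe sets, where chance gives 33.3%. Without a day 0 array the count changed little. It was larger without an array of either group compared, where that group holds 1 array. Called probe sets numbered 2 at a pseudocount of 100, 8 with the 60th percentile filter and 5 with trend and robust options.

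After Igha, the largest named increases were those of Saa3 (2.21 ± 0.23, adjusted p = 0.177), the lysosomal glucosidase Gaa (1.88, adjusted p = 0.385), Arg1 (1.77 ± 0.16, adjusted p = 0.144; 318 ± 20 against 58 ± 1) and the growth factor Nrtn (1.75, adjusted p = 0.340). The largest decreases were those of Cpb1, the pancreatic enzyme (−1.89, adjusted p = 0.177), Lce1h (−1.65, adjusted p = 0.305), Bik, which promotes cell death (−1.55, adjusted p = 0.305), the inflammatory cytokine Tnf (−1.43, adjusted p = 0.386; 116 ± 87 against 365 ± 26) and Ptgis, which makes prostacyclin (−1.42, adjusted p = 0.248). None of these 10 passed. Exocrine pancreas transcripts were lower than in isotype in 14 of 16 members, as in day 0, and the Gapdh ratio was higher on both day 3 arrays than on any other allogeneic array. With the filter at the 60th percentile Igha (adjusted p = 0.00636), Saa3 (0.0186), Arg1 (0.0131), Marco (0.0388) and Cpb1 (0.0229) did.

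Macrophage and monocyte markers were higher in 19 of 24 members (median 0.43, adjusted p = 2.5e-04; adjusted p = 0.360 with an estimated correlation), with 0 over all probe sets and, adjusted over the list alone, 10 higher and 2 lower, the lysozyme gene Lyz2 and the monocyte receptor Ccr2. Erythroid genes were higher in 15 of 16 members (median 0.38, adjusted p = 6.5e-04; adjusted p = 0.360 with an estimated correlation), with 0 adjusted over the list alone. B cell markers were lower in 13 of 15 members (median −0.37, adjusted p = 5.9e-05; adjusted p = 0.360 with an estimated correlation), with Cd79a, Cd22, Cd37 and the follicle homing receptor Cxcr5 past the threshold adjusted over the list alone. Glycolysis genes were lower in 13 of 15 members (median −0.22, adjusted p = 0.00651; 0.0656 without day 3 array 2, and 0.360 with an estimated correlation). Lower by calls that rested on single arrays were T cell markers (12 of 17 members, median −0.12, adjusted p = 0.0198; 0.557 without isotype array 1 and 0.0662 without day 3 array 2), MHC class II genes (7 of 9, median −0.33, adjusted p = 0.0198; 0.370 and 0.0662 without the same arrays) and helper T cell cytokines and regulators (12 of 18, median −0.22, adjusted p = 0.0399; 0.128 without isotype array 2 and 0.0662 without day 3 array 2). With an estimated correlation these 3 lists had an adjusted p = 0.360 each. The same held for type I interferon response genes (16 of 21 lower, median −0.13, adjusted p = 0.0413; 0.312 without isotype array 1, 0.145 without day 3 array 1, 0.0656 without day 3 array 2 and 0.360 with an estimated correlation). In these last 5 lists 0 members passed adjusted over the list alone. Quantile normalization ended the T cell and type I interferon calls (adjusted p = 0.0979 for each), and a pseudocount of 16 ended that of the helper list (0.0520).

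The other 16 lists did not pass for day 3 against isotype. Regulatory T cells and the interferon gamma response came closest (adjusted p = 0.0566 each), and cytotoxic effectors (0.758), proliferation (0.788), costimulation (0.133) and neutrophil and granule genes (0.643) lay further away. Median, mean and test differed in sign for the cytotoxic, MHC class I, p53 and strain haplotype lists, whose medians lay between −0.09 and 0.08. Cd4 was 1491 ± 165 against 2423 ± 16 (−0.69 ± 0.17, adjusted p = 0.364), Ifng was 1682 ± 24 against 2435 ± 244 (−0.52 ± 0.16, adjusted p = 0.402) and Icos was 3598 ± 205 against 4213 ± 240 (−0.23 ± 0.16, adjusted p = 0.657). Log2 changes of Gzmb (−0.08), Prf1 (−0.12), Icosl (−0.20), Foxp3 (0.08), Cd8a (0.07), Il4 (0.73) and Il10 (−0.27) did not pass either.

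The direct comparison of day 0 with day 3 arrays asks whether the start of the antibody matters. An earlier start also meant more injections and more antibody in total by day 4, which the comparison cannot separate from the start. Erythroid genes were lower in day 0 than in day 3 in 16 of 16 members, and helper T cell, macrophage and neutrophil lists were higher. None of these 4 calls held with an estimated correlation (adjusted p = 0.283 for erythroid genes and 0.321 for each of the others). Igha was 2838 ± 197 against 14454 ± 1093 (SD, n = 2; −2.33 ± 0.20, adjusted p = 0.0906), and Alas2 was 10 ± 3 against 99 ± 18 (−1.30, adjusted p = 0.356). Lyz2, the lysozyme gene of macrophages and neutrophils, was 1945 ± 58 against 935 ± 42 (1.02, adjusted p = 0.430). Limma called 0 of 15494 probe sets (smallest adjusted p = 0.0906), with 1058 at an unadjusted p under 0.05, where chance gives 775. At least 2-fold apart with arrays not overlapping were 182 probe sets, 70 higher and 112 lower in day 0. Arrays of the groups did not overlap for 39.1% of tested probe sets, where chance gives 33.3%. Without an isotype array the count changed little. It was larger without an array of either group compared, where that group holds 1 array. Called probe sets numbered 6 at a pseudocount of 100, 7 with the 60th percentile filter and 12 with trend and robust options. The Gapdh ratio also separated the groups (0.794 and 0.821 in day 0, 0.838 and 0.865 in day 3).

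The largest named increases in day 0 over day 3 were those of Zfp518b (1.84, adjusted p = 0.674), Lyz1 (1.59 ± 0.20, adjusted p = 0.235; 2186 ± 248 against 696 ± 133), Gtf2ird1 (1.49, adjusted p = 0.528), B3gnt3 (1.48, adjusted p = 0.589) and Raly (1.39, adjusted p = 0.356). Lyz1 and Lyz2 are nearly identical in sequence and their probe sets may share signal. After Igha the largest decreases were those of Sh3pxd2a (−1.71, adjusted p = 0.503), the retinoic acid receptor Rarg (−1.55), Cd1d2 (−1.54) and Msrb2 (−1.49, adjusted p = 0.410). Lyz1 (adjusted p = 0.0435) and Igha (0.00748) passed with the filter at the 60th percentile.

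Erythroid genes had a median log2 change of −0.61 (adjusted p = 2.9e-12; adjusted p = 0.283 with an estimated correlation), and 6 passed adjusted over the list alone: Alas2, Klf1, Ermap, Gata1, Epor and Tal1. Helper T cell cytokines and regulators were higher in 15 of 18 members (mean 0.29, adjusted p = 3.4e-04; adjusted p = 0.321 with an estimated correlation), with Ifng at 2596 ± 14 against 1682 ± 24 (0.61, adjusted p = 0.605), Tnf at 1.07 (adjusted p = 0.721) and Il10 at 0.96 (adjusted p = 0.605). Macrophage and monocyte markers were higher in 17 of 24 members (mean 0.24, adjusted p = 3.4e-04; adjusted p = 0.321 with an estimated correlation), and Lyz2 and Ms4a7 passed adjusted over the list alone. Neutrophil and granule genes were higher in 11 of 16 members (mean 0.19, adjusted p = 0.0156; adjusted p = 0.321 with an estimated correlation), with Ngp and Lcn2 past the threshold adjusted over the list alone. This last call ended without isotype array 2 (0.0513), day 0 array 1 (0.137), day 0 array 2 (0.0628) or day 3 array 2 (0.116). The other 20 lists did not pass, with costimulation and the interferon gamma response closest (adjusted p = 0.0681 each). Median, mean and test differed in sign for the B cell, megakaryocyte, p53, proliferation and strain haplotype lists. Icos (0.32, adjusted p = 0.758), Cd4 (0.38, adjusted p = 0.730), Gzmb (0.18), Prf1 (0.05), Icosl (0.17), Il4 (0.19), Foxp3 (−0.23) and Cd8a (−0.15) did not pass.

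Genes that differed between isotype and syngeneic arrays were followed into the treated groups by choosing them on 1 isotype array and measuring them against the other. This keeps the noise of a single array out of the measure. If both isotype arrays hold 1 RNA pool, a deviation of that pool stays in and would shift the chosen genes toward syngeneic without an effect of the antibody. Genes at least 4-fold lower in isotype than in syngeneic (228 and 250 probe sets chosen on array 1 and array 2) were higher than isotype by a median log2 of 0.21 in day 0, with 66.8% of them toward the syngeneic level, and by 0.15 in day 3, with 63.2%. Both medians for day 0 stood at percentile 100 of matched random lists, and those for day 3 at 100 and 99.38. Genes at least 4-fold higher in isotype (66 and 77 probe sets) had a median of 0.03 in day 0 (45.2% toward syngeneic, percentiles 83.26 and 69.03) and of −0.08 in day 3 (62.4%, percentiles 3.45 and 1.23). In simulation with no effect and independent noise on each array (5 draws), the 4 medians ran from −0.069 to 0.007. A shared isotype pool was not simulated. Chosen at 2-fold, the lower genes had medians of 0.071 and 0.100 in day 0 and day 3, and the higher genes in day 3 one of 0.001. At a pseudocount of 16 the higher genes in day 3 had a median of −0.004.

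The changes of the day 0 and day 3 groups from isotype correlated across probe sets (r = 0.564), which are not independent replicates, where shared isotype arrays alone gave 0.501 in simulation. Their covariance was 0.0677 against a simulated 0.0444, and it was 0.0171 with a separate isotype array for each group. At least 2-fold higher in both groups with arrays not overlapping were 44 probe sets, against a mean of 19.4 and a highest value of 32 in the 100 simulations with shared isotype arrays. At least 2-fold lower in both were 19, against a mean of 19.8 and a highest value of 31. The signs matched for 68.9% of probe sets against 66.7% in simulation. The simulations drew independent noise for each array. A deviation that both isotype arrays share from 1 RNA pool would raise the overlap and the covariance without an effect of the antibody. An excess over simulation therefore does not separate the 2.

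**Figure D3:**
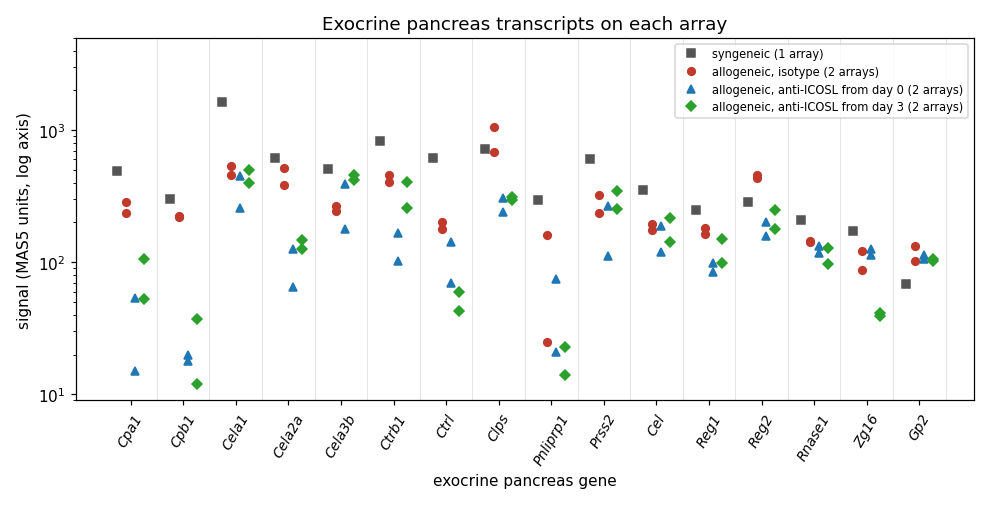
MAS5 signal of 16 exocrine pancreas transcripts on each of the 7 arrays by group, on a log axis, with 1 point per array. Their median is 419 on the syngeneic array, 227 and 233 on the isotype arrays, and 117 to 138 on the 4 anti-ICOSL arrays.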

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

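All values here compare the changes from isotype in the day 0 group with those in the day 3 group, as day 0 minus day 3 on the log2 scale. A camera test of this difference passed for 4 lists: erythroid genes (mean −0.636), helper T cell cytokines and regulators (0.288), macrophage and monocyte markers (0.238) and neutrophil and granule genes (0.192). None of the 4 passed with an estimated correlation, where the smallest adjusted p was 0.283.

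The remaining results were singled out because both day 0 arrays lay on one side of both isotype arrays and both day 3 arrays on the other, a criterion that does not test the difference. None of them passed in the direct comparison by limma over all probe sets or by camera, while Ermap, Tal1, Gata1, Klf1, Lyz2, Lcn2 and Ngp passed adjusted over their list alone. The interferon gamma response list differed by 0.123 (camera adjusted p = 0.0681). Icos differed by 0.319 (limma adjusted p = 0.758). Among erythroid genes, Ermap differed by −0.675, Tal1 by −0.887, Gata1 by −0.563 and Klf1 by −0.668. Among lysozyme and neutrophil genes, Lyz1 differed by 1.592 (adjusted p = 0.235), Lyz2 by 1.019 (0.430), Lcn2 by 0.981 (0.578) and Ngp by 0.739 (0.552). Msrb2, a methionine sulfoxide reductase, differed by −1.489 (0.410) and Sh3pxd2a, a scaffold protein, by −1.708 (0.503).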

How the results depend on the processing

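Each setting was changed alone. For isotype against syngeneic, named genes stayed past the threshold or short of it in 991 of the recomputed values, lost their call in 143, gained one in 14 and reversed in 1. List calls held in 129 recomputed values and were lost in 14. For day 0 against isotype, day 3 against isotype and day 0 against day 3, genes held in 646, 785 and 557 values, gained a call in 12, 8 and 7 and reversed in 6, 7 and 2, and lists held in 44, 67 and 36 values and lost their call in 11, 21 and 8. The cause of a change was not tested except where fewer arrays or another number of tested probe sets gave it by construction.

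The number of called probe sets for isotype against syngeneic was 542 without a filter and 1627 with the filter at the 60th percentile, where more or fewer probe sets were tested. It was 318 with only the compared groups, 406 to 679 with 1 array left out, where fewer arrays were used, 811 with the replicate number as a block, and 1780 with trend and robust options. The replicate numbers do not pair arrays (correlations of −0.010, 0.078 and 0.040). For day 0 against isotype, day 3 against isotype and day 0 against day 3, the pseudocount of 100 gave 4, 2 and 6 called probe sets, the 60th percentile 13, 8 and 7, trend and robust options 21, 5 and 12, and the block 0 each. With an estimated correlation, 0 lists passed in each of the 4 comparisons. Fry gave an unadjusted p under 0.05 for most lists called at the preset correlation. The exceptions were erythroid genes in day 0 against isotype (0.0546), and helper genes (0.129) and T cell markers (0.271) in day 3 against isotype. Some lists that camera did not call also had such a p by fry. For isotype against syngeneic these include regulatory T cells (0.00483), mast cells (0.00577) and the p53 response (0.0199). With 1 array left out, 2 to 7 lists passed for day 0 against isotype and 3 to 8 for day 3 against isotype. Probe sets at least 2-fold apart with arrays not overlapping numbered 1707 for isotype against syngeneic, 2438 at a pseudocount of 16, 1134 at a pseudocount of 100 and 1704 to 2349 with 1 array left out. For the other 3 comparisons they numbered 530, 699 and 500 at a pseudocount of 16, 49, 64 and 34 at a pseudocount of 100, and 200 to 606, 285 to 780 and 178 to 572 with 1 array left out. These counts follow the signal over background, since a smaller pseudocount lets low signals pass 2-fold.

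The shift of genes higher in isotype was 0.001 in day 3, of the opposite sign, when genes were chosen at 2-fold, −0.075 with quantile normalization and −0.004 at a pseudocount of 16, and 0.006 in day 0 at a pseudocount of 16. The shift of genes lower in isotype was 0.071 in day 0 and 0.100 in day 3 when chosen at 2-fold, and in day 3 it was 0.102 with quantile normalization and 0.214 at a pseudocount of 16. With 1 array left out, changes that had not passed crossed 0. Cd8a ran from −0.668 to 0.376 for isotype against syngeneic, from −0.602 to 0.443 for day 0 against isotype, from −0.453 to 0.592 for day 3 against isotype and from −0.475 to 0.178 for day 0 against day 3. For day 0 against isotype, Gzmb ran from −0.016 to 0.219, Ifng from −0.006 to 0.195 and Icosl from −0.196 to 0.129. For day 3 against isotype, Gzmb ran from −0.195 to 0.040, Prf1 from −0.271 to 0.034, Il10 from −0.566 to 0.019 and Foxp3 from −0.010 to 0.237. Prf1 ran from −0.101 to 0.204 for day 0 against day 3. Chosen after the data were seen, leaving out MHC and immunoglobulin genes gave 987 called probe sets for isotype against syngeneic, and leaving out exocrine pancreas transcripts gave 0 for each treated group against isotype.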

Other observations

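Natural killer genes did not pass as a list in either treated group (camera adjusted p = 0.136 in day 0 and 0.535 in day 3). Their activating receptor Ncr1 was 726 ± 119 in day 0 against 348 ± 57 in isotype (SD, n = 2; log2 change 0.96, limma adjusted p = 0.459) and 464 on the syngeneic array. Megakaryocyte and platelet genes were higher in 6 of 9 members in both day 0 (median 0.34, adjusted p = 0.164) and day 3 (median 0.29, adjusted p = 0.160). Pf4, a chemokine of platelets, was 410 and 427 on the day 0 arrays and 394 and 474 on the day 3 arrays against 238 and 262 on the isotype arrays, with 427 on the syngeneic array. Stroma and endothelium genes did not pass (0.423 in day 0 and 0.198 in day 3), and Cxcl13, the chemokine that draws B cells into follicles, had a log2 change of 1.33 in day 3 (adjusted p = 0.403).

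Apart from Igha, the single genes of this paragraph were chosen after their values were seen, and none passed over all probe sets for either treated group against isotype. Bcl6, a transcriptional repressor of lymphocytes, was 164 in day 0 and 162 in day 3 against 305 in isotype (log2 changes −0.74 and −0.72, limma adjusted p = 0.672 and 0.459), with 144 on the syngeneic array. A further probe set of Bcl6 gave log2 changes of −0.09 and −0.31. Cxcr5, the receptor for Cxcl13, changed by −0.79 and −0.83 (adjusted p = 0.576 and 0.383), and passed in day 3 adjusted over the B cell list alone. The isotype arrays themselves stood at 1240 and 1853. Izumo1r, a member of the regulatory T cell list, changed by −0.71 and −0.36 (adjusted p = 0.580 and 0.600). The cytokine Il21 was 449 ± 33 in day 0 and 469 ± 146 in day 3 against 420 ± 117 in isotype (SD, n = 2). Pdcd1 was 1030 ± 439 and 1124 ± 362 against 1100 ± 243, and Cxcl13 was 307 ± 184 and 480 ± 165 against 160 ± 60. Igha was 2446 and 1788 on the isotype arrays, 2698 and 2977 on the day 0 arrays, and 15228 and 13681 on the day 3 arrays, with 46620 on the syngeneic array.

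The tests of explanations in the following 3 paragraphs were chosen after the result was seen. The camera calls of the macrophage list, and the settings that leave out an array, were fixed before.

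Exocrine pancreas transcripts were lower than isotype in 14 of 16 members in both treated groups (medians −0.59 and −0.57). Noise of a single isotype array was argued against, since the median closest to 0 with 1 isotype array left out was −0.427. Pancreatic tissue taken along with the spleen in unequal amounts may account for the pattern: 11 further transcripts, besides those that drew attention, had medians of −0.42 and −0.26, and the higher of their percentiles among 10000 matched random lists was 0.28. The most abundant members did not move in 1 ratio, which such a carry-over leaves unaccounted for: Clps was 1050 and 681 on the isotype arrays, 242 and 307 in day 0 and 313 and 294 in day 3, while Cela1 was 532 and 457, 256 and 448, and 400 and 500. A change in the recipients' tissue was not tested and stays open.

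Macrophage and monocyte markers were higher than isotype in both treated groups at camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.168 in day 0 and 0.360 in day 3). A lower share of lymphocytes as the only change, which would raise the markers of every other cell type alike, was argued against. In day 0 macrophage markers exceeded erythroid genes with a 95% bootstrap lower bound of 0.610. In day 3 they exceeded neutrophil genes with a lower bound of 0.144, although macrophage and erythroid genes moved alike in day 3 (−0.03, interval −0.23 to 0.19). The bootstrap over genes takes them as independent. A lower share of lymphocytes together with a change in another cell type was not tested and stays open. B cell and T cell lists had mean log2 changes of −0.338 and −0.099 in day 0, and of −0.353 and −0.149 in day 3. Noise of a single isotype array was also argued against, since without either one the list's median stayed at 0.54 to 0.61 in day 0 and 0.39 to 0.42 in day 3 (highest adjusted p = 0.00622 at the preset correlation). A pool of isotype RNA that held few macrophages by chance cannot be told apart from an effect of the antibody, because the isotype arrays, which differed by 0.007, may share 1 pool.

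Large differences between allogeneic and syngeneic arrays follow the donor strain, because C3H cells are present on the allogeneic arrays only. A sequence difference under the probes changes its own probe set and leaves further probe sets of the gene as they were. In 231 genes called lower outside the MHC, further probe sets had a median log2 change of −0.860 (95% bootstrap interval −0.96 to −0.74) against −1.54 for the leading ones and were lower in 214, but the interval did not lie below −0.77, the bound set for the test, and 252 called lower genes with 1 probe set were not covered, so this explanation stays open. In MHC genes as a set it also stays open, since 1 of 4, H2-D1, had a further probe set at least 2-fold the opposite way, against 4 of 384 other genes (Fisher's exact test, two-sided, p = 0.0508). The H2-D1 probe sets that passed had log2 changes of 5.306 and 1.960 against −2.573, −2.744, −2.470 and −2.195. For H2-D1 these values argue against a change in the level of 1 transcript alone. Strain differences in expression and the allogeneic response itself were not separated by the design.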
